A study of Mus musculus with 12 samples.

How the data were processed

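Gene expression was measured with Affymetrix Mouse Genome 430 2.0 arrays in small vessel fragments isolated from cerebrum and cerebellum. Each of the 12 arrays held the RNA of 1 region of 1 mouse. The 6 mice, on a C57BL/6 background, were 2 months old, and each genotype (Notch3 knockout and littermate control) had 3. Replicates were therefore separate mice, per the design text. The replicate number in a title was taken as the mouse, which the labels do not state in words. Biotinylated cRNA was made from a small amount of RNA with an amplification protocol, per the labels. How the vessel fragments were isolated, where in Notch3 the deletion lies and how the knockout line was made are not given in the sources used here.

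The deposited values are log2 expression values per probe set, made by the authors with GCRMA 2.32.0, which corrects background, normalises between arrays and summarises the probes of a set, per the submitters' processing notes. These values were used as deposited and were not rescaled. The table held 45101 probe sets, of which 34958 named exactly 1 gene in the annotation used here, 932 named several and 9211 named none; 64 of the last were the array maker's control probe sets and were left out. The deposited table carries no calls of detection and no genome build. Gene positions came from a mouse gene table and were used only to find neighbours of Notch3, so no coordinates are printed. The precision is limited by the number of arrays.

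A probe set was kept when at least 3 of the 12 arrays exceeded the median of all values, 3.27. Among probe sets that named exactly 1 gene, the one with the highest mean over the 12 arrays stood for its gene, which left 11716 genes. Tests were made with limma 3.58.1 on R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene past this threshold is said below to be called. The knockout was compared with the control in cerebral vessels and in cerebellar vessels, the regions were compared within each genotype, and the difference of the knockout effect between regions (cerebellar minus cerebral) was tested. These fits used 4 group means over all 12 arrays, with 8 residual degrees of freedom. Because the regions of a mouse are not independent, the knockout was also compared on the mean of both regions per mouse, 3 against 3, with 4 residual degrees of freedom. Where every array of the dimmer group lay at or under 3.27, the fold was computed against at least that value and is given as "at least". Where 2 of 3 did, these were raised to that value, and the log2 change is not exact; 1 of 3 did for Dpep1, for Nfkbid and Liph in knockout mice and for Cxcl2 in controls.

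A set of 29 gene lists was written for the cell types and pathways that a brain vessel preparation can hold; 28 had at least 5 tested genes and were tested. Each was tested with limma's camera at its preset correlation between genes, again with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance. Adjustment ran over the lists of a comparison. Grip2, Nrip2, Susd5, Ldb3 and Casq2 entered the smooth muscle list, and the first 2 of them also the Notch target list, from general knowledge that may rest on earlier work on vessels without Notch3, possibly on these very samples. Their counts are therefore not independent evidence of a direction, and each list was also tested without them. The list of transcripts linked to sex had 4 tested genes and was used only to check the labels.

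Genes were named by a fixed rule. Notch3 came first, with each of its probe sets. For each comparison the rule then took the 12 genes higher and the 12 lower with the largest change among called genes whose 3 values in one group all lay above the 3 of the other. For the difference between regions it took 6 and 6, and, since fewer than 10 genes qualified there, also the 10 smallest p, given as values only. From each list it took up to 4 members with the largest change, called members first. Genes with clone names were counted but not named. The comparisons, tests, filter, lists, naming rule and main alternatives were fixed before the data were examined. Members named beyond that rule, such as list members that were not called, were chosen after their values were seen.

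The enrichment of called genes near Notch3 was tested with Fisher's exact test, two-sided, in a window of 20 Mb to each side, among the 11681 tested genes that the gene table places on a chromosome, Notch3 itself left out. The agreement between regions was Pearson's r across all tested genes of the log2 fold changes, given without a p. Alternatives covered the filter, the choice of probe sets, the scaling between arrays, the variance model, array weights, the arrays in the fit, blocks for replicate number or mouse, the window and the leaving out of each array or mouse. Added after the data had been seen were a covariate for Xist, the counts of called list members under each alternative, the lists without the genes named above, and the ion channel list without Cacna1h, a neighbour of Notch3. The self-test ran the same code on data simulated with the spread of the arrays and 200 changed genes. For the cerebral comparison it recovered 74.6% of changes of 0.5 log2, 97.0% of 1 and 98.5% of 2, with 7.22% of the calls false. For the cerebellar comparison the shares were 73.1%, 95.5% and 97.0%, with 5.35% false. On mouse means they were 65.7%, 98.5% and 97.0%, with 3.33% false. Between regions they were 68.7%, 91.0% and 100%, and for the difference between regions 35.8%, 86.6% and 98.5%, with 0 false calls in either. A simulated list of 40 genes shifted by 0.3 log2 was called, and 0 of 100 others were. Lists whose genes move together were not covered. Figures were drawn with matplotlib 3.10.9.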

Results

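Gene expression profiles were collected from small vessel fragments of the cerebrum and of the cerebellum of the same mice, which lacked Notch3 or were littermate controls. Notch3 is a receptor of vascular smooth muscle cells and pericytes, the mural cells that wrap small vessels. The 12 arrays formed 4 groups of 3: control cerebral, control cerebellar, knockout cerebral and knockout cerebellar. Array medians lay between 3.24 and 3.30 log2, and single values ranged from 0.690 to 16.3. Arrays of one group correlated with r from 0.991 to 0.996 across the 11716 tested genes, and arrays of different groups with r from 0.975 to 0.994. The first principal component held 37.6% of the variance and the second 25.7%. Xist, a female transcript, was at 12.9 to 13.3 in 8 arrays and at or under 2.87 in the other 4. Eif2s3y, a gene of the Y chromosome, was at or above 10.5 in those 4 arrays and at or under 3.11 in the 8 with Xist. Both regions matched in 6 of 6 mice, and each genotype had 2 mice with Xist and 1 (control 3, knockout 2) without.

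The first check was whether Notch3 itself was lost. With its brighter probe set, control arrays read 10.84 to 11.61 in cerebral and 11.73 to 12.02 in cerebellar vessels, and knockout arrays read 2.48 to 3.58. Its other probe set read 6.74 to 8.21 in controls and 2.21 to 3.76 in knockouts. The median of all values was 3.27, so the knockout arrays sat near background and matched their labels. The log2 fold change was -8.55 (SE 0.29, n = 3 arrays per group, adjusted p = 9.94e-08) in cerebral vessels, at least 253-fold lower. It was -8.77 (SE 0.29, adjusted p = 7.70e-08), at least 354-fold lower, in cerebellar vessels and -8.66 (SE 0.14, adjusted p = 3.25e-06), at least 310-fold lower, on the mean of both regions per mouse.

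**Figure D1:**
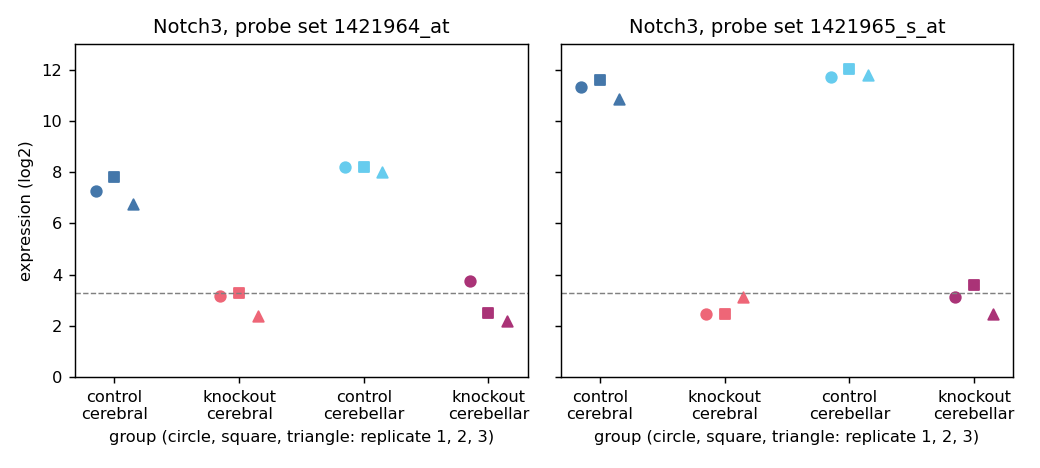
Expression of Notch3 (log2) on each of the 12 arrays by each of its probe sets, with groups on the horizontal axis, a symbol for each replicate and a dashed line at the median of all values, 3.27.

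The knockout was compared with the control in cerebral vessels to see what the vessels lost or gained without the receptor. Vascular smooth muscle genes were lower in knockout vessels (32 of 40 markers; adjusted p = 0.0788 with an estimated correlation). Casq2, the calcium-storing protein calsequestrin, fell by 3.26 log2 (SE 0.19, n = 3 arrays per group), and Myh11, the smooth muscle myosin heavy chain, fell by 1.70 (SE 0.16). Cacna1h, a T-type calcium channel whose gene lies within 20 Mb of Notch3, fell by 3.71 (SE 0.17), at least 7.47-fold; an effect of its place on this value was not excluded. Endothelial markers had a median log2 fold change of 0.05. Microglia markers, of the immune cells of brain tissue, had a median of 0.79, with 10 of 25 called higher and the list not called with an estimated correlation (adjusted p = 0.256).

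The other large changes were in genes of mixed function. Ang, the secreted ribonuclease angiogenin, rose by 9.08 log2 (SE 0.19, adjusted p = 1.48e-09), at least 373-fold, and its 3 probe sets gave 10.66, 9.08 and 3.75. Rpgrip1, a protein of the photoreceptor cilium, rose by 4.51 and Eme2, a subunit of a DNA endonuclease, by 3.67, although a second probe set of Eme2 read 0.05 and was not called. Also higher were Liph (3.02, at least 6.88-fold with 2 of 3 control arrays at or under 3.27), Glrp1 (2.86), H2-DMa, which serves peptide loading of class II molecules (2.60), Lrmda (2.56, at least 4.82-fold), the heme-binding Hebp1 (2.55), Lpxn (2.48), the leukocyte receptor Cd84 (2.43), Ap1s3 (2.35, at least 3.85-fold) and Zfp994 (2.19). Ccr6, a chemokine receptor, had a log2 fold change of -7.17 (SE 0.13, adjusted p = 5.54e-10), at least 81.2-fold lower, and Adamdec1, a protease of the ADAM family, one of -6.49 (SE 0.49), at least 31.3-fold lower. Ephx3, an epoxide hydrolase, was at -4.17, C1s1, a complement protease, at -3.42, Cyp2e1, a cytochrome P450, at -3.15 and Synpo2l at -3.08, at least 4.25-fold lower. Slc22a2, an organic cation transporter, was at -2.77, at least 5.03-fold lower, and Tmem242 was at -2.69, while a second probe set of Tmem242 rose by 0.74.

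Of 40 tested vascular smooth muscle markers 32 fell, 0 rose and 8 were not called, and adjusted over the list alone 36 fell. Casq2 (-3.26), Susd5 (-3.21), Ldb3 (-2.47) and Grip2 (-2.39) led. Cnn1 (-2.22) and Tagln (-0.86), actin-binding proteins of contractile cells, fell as well, and so did Acta2, smooth muscle actin, by a small step (-0.39). The list's median was -1.03 (camera adjusted p = 5.12e-34; adjusted p = 0.0788 with an estimated correlation; fry adjusted p = 7.25e-05). Some members were listed from knowledge that may rest on vessels without Notch3, so the count is not independent evidence. Without those 5 genes 27 of 35 fell, with a median of -0.86. Of 20 smooth muscle ion channel genes 7 fell and 13 were not called (10 lower and 1 higher adjusted over the list alone), with a median of -0.35 (camera adjusted p = 3.87e-08; adjusted p = 0.0788 with an estimated correlation). Without Cacna1h 6 of 19 fell (camera adjusted p = 1.42e-06). After it came Kcnab1 (-2.43), phospholamban (Pln, -2.23) and Kcnma1 (-2.02), the pore of the large-conductance potassium channel. Pln and Kcnmb1 stand in both of these lists. Of 27 pericyte markers 15 fell and 12 were not called (23 lower adjusted over the list alone), with a median of -0.59 (camera adjusted p = 9.12e-17; adjusted p = 0.0788 with an estimated correlation). Ndufa4l2 (-1.55), Art3 (-1.43), Enpep (-1.35) and Rarres2 (-1.30) led. Kcnj8 and Abcc9, which form the potassium channel of pericytes, and Rgs5 were not called.

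Among Notch target genes 6 of 18 fell and 1, Gata2 (0.41), rose (7 lower and 1 higher adjusted over the list alone). Grip2 (-2.39), Nrip2 (-2.34), Hey2 (-1.13) and Nrarp (-1.07) led, and the list's median was -0.24 (camera adjusted p = 0.0136; adjusted p = 0.0947 with an estimated correlation). Grip2 and Nrip2 are also in the smooth muscle list and are 2 of the genes whose place may rest on earlier work, so this count is not independent evidence. Without them 4 of 16 fell, 1 rose, and the list was no longer called (camera adjusted p = 0.312). Of 23 Notch receptors and ligands, Notch3 itself and Dtx3 (-0.54) fell and Numb, an inhibitor of Notch signalling, rose by 0.35. With adjustment within the list 3 were lower and 1 higher, and camera did not call the list (adjusted p = 0.451). Of 23 PDGF and VEGF signalling genes 5 fell, among them Pgf (-1.37), S1pr3 (-1.17) and Angpt1 (-0.79), and Pdgfb rose by 0.31. The list alone gave 6 lower and 2 higher (camera adjusted p = 0.148). Of 24 TGF-beta and BMP genes Tgfb3 fell (-0.98) and Tgfbr1 rose (0.64), with 3 lower and 2 higher adjusted over the list alone.

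Microglia markers rose in 10 of 25 cases, 15 were not called, and 25 of 25 had a positive fold change; 23 were higher adjusted over the list alone. Tmem119 (1.16), Trem2 (1.13), C1qa (1.01) and P2ry13 (0.99) led (camera adjusted p = 2.75e-16; adjusted p = 0.256 with an estimated correlation; fry adjusted p = 0.0174). The count of 10 became 4 without control cerebral replicate 1, 1 without replicate 2, 2 without knockout cerebral replicate 1, 20 without replicate 2 and 1 without replicate 3. It was 4 with no filter, 0 with only the 6 cerebral arrays in the fit and 22 with the replicate block. Immediate early and stress genes, which also respond to handling of tissue, fell in 6 of 26 cases and rose in 1 (8 lower and 1 higher adjusted over the list alone; median -0.21, camera adjusted p = 0.00167; adjusted p = 0.116 with an estimated correlation). Nr4a1 (-1.42), Hspa1a (-1.29), Atf3 (-1.10) and Hspb1 (-0.54) fell, and Gadd45b rose by 0.77. The 7 calls became 1 without control cerebral replicate 1 or knockout cerebral replicate 3, 3 without control replicate 3 or knockout replicate 1, and 2 with no filter or with only the 6 cerebral arrays. Interferon response genes had a median of -0.21 and 1 of 27, Tap1 (-0.50), fell (also 1 adjusted over the list alone; camera adjusted p = 0.00167; adjusted p = 0.897 with an estimated correlation). Its call was lost in every run without 1 array except that without knockout cerebral replicate 2, which called 2. With only the 6 cerebral arrays it was lost as well, and 2 were called with array weights or the Xist covariate. None of 22 hypoxia genes was called by limma (5 at an unadjusted p under 0.05), while camera called the list upward at a median of 0.07 (adjusted p = 0.0399; adjusted p = 0.116 with an estimated correlation). With an estimated correlation camera called 0 lists in this comparison, with 6 at an unadjusted p under 0.05, and fry called 9.

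The other lists were not called by camera in cerebral vessels. Of 33 endothelial markers 1, the transcription factor Ets1 (-0.92), fell (1 adjusted over the list alone), and 0 of 34 blood-brain barrier genes were called by limma (3 at an unadjusted p under 0.05), with a median of 0.00. Among 36 fibroblast and fibrillar matrix genes 3 rose and 3 fell (4 and 5 adjusted over the list alone): the collagens Col6a1 (1.46), Col6a2 (1.02) and Col3a1 (0.71) against Tagln, a smooth muscle gene as well (-0.86), Slc6a13 (-0.77) and Serping1 (-0.72). Single members were called in the lists of basement membrane (Col4a5, -0.51, of 27), neurons (Map2, -0.67, of 20), cerebellar neurons (Zic1, -0.59, of 14), forebrain neurons (Nr4a2, -0.91, of 9), astrocytes (Atp1b2, -0.73, of 21) and choroid plexus (Rarres2, also a pericyte marker, of 19). Adjusted over the list alone these numbered 4 lower and 1 higher, 0, 1, 2, 1 and 1. Zic1 was not called in the runs without control cerebral replicate 1 or 2 or knockout cerebral replicate 1 or 3, while Col4a5's list gained a member without control replicate 2 or 3 and the astrocyte list without knockout replicate 1 or 3. In the Wnt list Nkd1 fell (-0.74) and Fgfbp1 rose (0.61) among 16 genes (4 and 2 adjusted over the list alone). Limma called 0 of 19 endothelial leak, 22 arterial, 16 venous, 8 cell cycle, 11 oligodendrocyte, 16 leukocyte and 6 red blood cell and platelet genes; unadjusted p under 0.05 held for 2, 6, 2, 2, 2, 2 and 0 of them. Adjusted over the list alone 1 arterial gene was higher and 2 were lower, and the other lists here had 0. Settings moved several of these small counts. Astrocyte calls were 2 with the mean of probe sets, with trend and robust eBayes or with the Xist covariate, 3 with the replicate block and 6 with array weights. Endothelial calls were 2 with trend and robust eBayes or the replicate block and 3 with array weights, and blood-brain barrier calls 3 with the replicate block and 1 with array weights. Zic1 was not called with no filter, with centred or quantile-normalised arrays or with only the 6 cerebral arrays. Basement membrane calls were 0 with the mean of probe sets, 2 with trend and robust eBayes, 3 with the replicate block or the mouse as random replicate block and 4 with the 75th percentile filter, array weights or the Xist covariate. Median and mean differed in sign for the Wnt (0.01 and -0.03), arterial (0.06 and -0.02), TGF-beta (0.04 and -0.05) and forebrain neuron lists (0.02 and -0.05), and for neurons the median (-0.01) and the direction of the test, upward, did.

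In all, limma called 748 of 11716 genes in cerebral vessels, 287 higher and 461 lower, and 226 of them changed more than 2-fold. The groups did not overlap for 24.4% of all genes, against 10% by chance. For Notch3 knockout against control in cerebral microvessels the lower genes made up 61.6% of the calls, but 51.0% with arrays centred on their medians and 52.1% after quantile normalization. Replicates with the same number correlated across genotypes (r of 0.129, 0.342 and 0.141 between deviations from the group means), and a fit with the number as replicate block called 1127 genes. The count was 484 without control cerebral replicate 1, 450 without knockout cerebral replicate 1 and 439 without knockout cerebral replicate 3, and 310 with only the 6 cerebral arrays in the fit, where Liph, Cd84 and Cyp2e1 were no longer called. It was 1164 with every probe set on its own and 1415 with array weights.

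**Figure D2:**
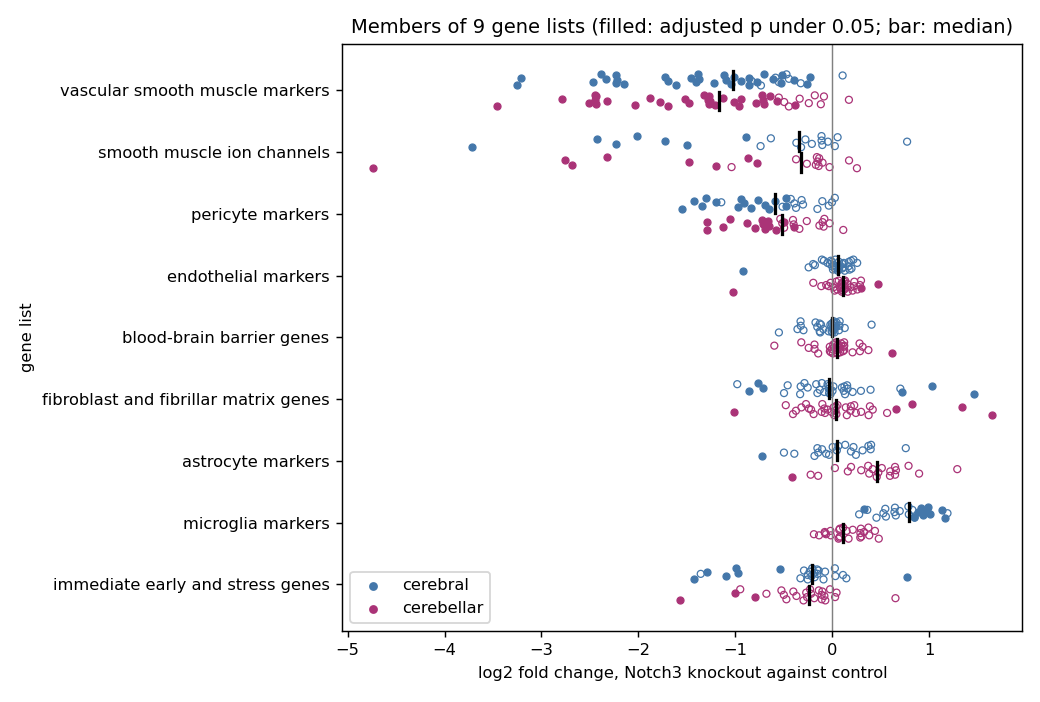
Log2 fold change of each tested member of 9 gene lists, knockout against control, in cerebral (blue) and cerebellar (purple) vessels; filled points are called members and bars are list medians.

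The same comparison was made in cerebellar vessels. Smooth muscle genes were again lower: Myh11 fell by 1.78 log2 (SE 0.16, n = 3 arrays per group) and Kcnma1 by 2.76 (SE 0.17), and Srl, a sarcoplasmic calcium-binding protein, fell by 2.86 (SE 0.20). Cacna1h, a neighbour of Notch3, fell by 4.74 (SE 0.17), at least 20.9-fold, and an effect of its place was not excluded. Ang rose by 8.34 (SE 0.19), at least 220-fold, Rpgrip1 by 5.05 (SE 0.20) and Eme2 by 3.49, with 0.13 on its second probe set. Of 14 markers of neurons of the cerebellum 3 rose (adjusted p = 0.226 with an estimated correlation), with Pvalb, the calcium buffer parvalbumin, higher by 1.85 (SE 0.25), at least 3.07-fold with 2 of 3 control arrays at or under 3.27. Further higher genes were the dipeptidase Dpep1 (2.74), Lrmda (2.44, at least 4.06-fold), Fez1 (2.37), the amidating enzyme Pam (2.37), Hddc3 (2.31), Hebp1 (2.09) and Zfp994 (2.00). Ccr6 was at -6.65, at least 52.6-fold lower, Adamdec1 at -5.73, at least 18.5-fold lower, Ephx3 at -4.63 and Synpo2l at -4.28, at least 10.7-fold lower. Also lower were Cyp2e1 (-3.53), Susd5 (-3.45), C1s1 (-3.30), the orphan receptor Gpr20 (-2.88) and Lrrc10b (-2.83, at least 4.25-fold lower). Dpep1 was not called in the runs without control cerebellar replicate 1 or 3 or any knockout cerebellar replicate, with no filter, with array weights or with only the 6 cerebellar arrays. Lrrc10b was not called without any one knockout replicate, with no filter or with only those 6 arrays.

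Of 40 smooth muscle markers 31 fell, 0 rose and 9 were not called in cerebellar vessels (34 lower adjusted over the list alone), with a median of -1.17 (camera adjusted p = 9.28e-40; adjusted p = 0.0457 with an estimated correlation; fry adjusted p = 7.69e-05). Susd5 (-3.45), Grip2 (-2.79), Casq2 (-2.51) and Ldb3 (-2.45) led, and Myh11 was at -1.78. Without the 5 genes that may come from earlier work, which are no independent evidence, 26 of 35 fell (camera adjusted p = 2.35e-32; adjusted p = 0.0569 with an estimated correlation). Of 20 ion channel genes 8 fell (11 lower and 1 higher adjusted over the list alone), led by Cacna1h, Kcnma1 (-2.76), Kcnab1 (-2.69) and Pln (-2.33), and the list was called with the preset and with an estimated correlation (adjusted p = 3.70e-11 and 0.0355), as it was without Cacna1h, with 7 of 19 lower (adjusted p = 4.92e-09 and 0.0457). With the filter at the 75th percentile 3 channels were called here and 3 in cerebral vessels. Pericyte markers fell in 14 of 27 cases (19 adjusted over the list alone), led by Ndufa4l2 (-1.29), Ifitm1 (-1.29), Enpep (-1.13) and Art3 (-1.06), with a median of -0.52 (camera adjusted p = 7.73e-17; adjusted p = 0.0569 with an estimated correlation). The 14 became 9 without control cerebellar replicate 1, 8 without control replicate 2, 8 without knockout cerebellar replicate 3, and 9 with no filter or with only the 6 cerebellar arrays. Of 18 Notch targets 5 fell (8 lower and 1 higher adjusted over the list alone): Grip2 (-2.79), Nrip2 (-2.44), Nrarp (-1.36), Hey2 (-1.22) and Heyl. The list was called with the preset and with an estimated correlation (adjusted p = 0.00141 and 0.0457). Without Grip2 and Nrip2, no independent evidence as above, 3 of 16 fell and it was not (camera adjusted p = 0.0933).

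Immediate early and stress genes were lower in cerebellar vessels too, with 3 of 26 called, Fosb (-1.57), Fosl2 (-1.01) and Atf3 (-0.80), and 6 lower and 1 higher adjusted over the list alone (median -0.25, camera adjusted p = 1.03e-04; adjusted p = 0.0569 with an estimated correlation). The 3 calls became 0 without control cerebellar replicate 1 or 3 or knockout cerebellar replicate 3, and 1 without knockout cerebellar replicate 2; they became 0 with only the 6 cerebellar arrays, 1 with no filter and 5 with the Xist covariate. Of 14 cerebellar neuron markers 3 rose, Pvalb, Calb1 (1.45) and Gabra6, a GABA receptor subunit of granule cells (1.43), and adjusted over the list alone 5 were higher and 1 lower (camera adjusted p = 0.0303; adjusted p = 0.226 with an estimated correlation). Here 5 rose without knockout cerebellar replicate 2, with array weights or with the replicate block, and 0 were called with the 75th percentile filter. Astrocyte markers had a median of 0.46, yet 1 of 21 was called and it fell, Atp1b2 (-0.42), with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.95e-04; adjusted p = 0.564 with an estimated correlation). It was not called without control cerebellar replicate 2 or any one knockout replicate, and 0 astrocyte markers were called with no filter, the Xist covariate or either replicate block, 2 with the mean of probe sets or trend and robust eBayes and 3 with array weights or only the 6 cerebellar arrays. Of 33 endothelial markers Sox18 (0.47) and Sox17 (0.30) rose and Ets1 (-1.02) fell, as they did adjusted over the list alone, at a median of 0.11 (camera adjusted p = 0.00114; adjusted p = 0.368 with an estimated correlation). Of 25 microglia markers limma called 0 (1 at an unadjusted p under 0.05; 0 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.0791), and 1 with the replicate block.

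The remaining lists were not called by camera in cerebellar vessels. Fibroblast genes again held rising collagens, Col6a1 (1.64), Col6a2 (1.34) and Col3a1 (0.82), with Ogn, and Tagln fell (-1.02; 5 of 36 called, 4 higher and 3 lower adjusted over the list alone). Pgf (-1.32), S1pr3 (-1.03), Angpt1 (-0.69) and Pdgfa (-0.59) fell and Pdgfb rose (0.38) among 23 PDGF and VEGF genes (6 and 1 adjusted over the list alone). Tgfb3 (-1.17) and Bmp4 (-0.70) fell and Smad6 rose (0.94) among 24 TGF-beta genes (3 and 3 adjusted over the list alone). Notch3 fell and Notch4, an endothelial receptor, rose by 0.50 among 23 receptors and ligands (2 and 1 adjusted over the list alone). Single calls were Tfrc, the transferrin receptor (0.61), of 34 blood-brain barrier genes, Lama1 (1.15) of 27 basement membrane genes, Sox17 of 22 arterial markers, Drd1 (-1.10) of 9 forebrain neuron markers and Rarres2 (-0.72) of 19 choroid plexus markers. Tfrc was not called without control cerebellar replicate 2 or 3 or knockout replicate 1 or 2, nor Lama1 without control replicate 2 or 3 or knockout replicate 1 or 3. Blood-brain barrier calls were 0 with no filter, the mean of probe sets or only the 6 cerebellar arrays and 2 with array weights or the replicate block. Basement membrane calls were 0 with no filter or only those 6 arrays and 3 with array weights, and the Xist covariate called 1 interferon gene. The choroid plexus count was 2 without knockout replicate 1 and the basement membrane count 2 without knockout replicate 2. In the Wnt list Sox17 rose and Adgra2 (-0.27) fell among 16 genes. Of 20 neuron markers Pvalb rose and Map2 (-0.74) fell. Adjusted over the list alone these 7 lists gave 1, 2, 1, 0, 0, 1 and 1 higher and 0, 3, 0, 3, 1, 2 and 1 lower. Limma called 0 of 27 interferon, 22 hypoxia, 19 endothelial leak, 16 venous, 8 cell cycle, 11 oligodendrocyte, 16 leukocyte and 6 red blood cell and platelet genes, with 3, 4, 2, 3, 1, 1, 0 and 0 at an unadjusted p under 0.05. Adjusted over the list alone 2 hypoxia genes were higher and 1 lower, and 1 venous gene was lower. Median and mean differed in sign for Notch receptors (0.00 and -0.37), endothelial leak (0.07 and -0.02), arterial (0.09 and -0.01), venous (0.01 and -0.04), TGF-beta (0.03 and -0.02), PDGF and VEGF (0.01 and -0.14), leukocyte (-0.01 and 0.07) and red blood cell lists (-0.01 and 0.03).

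Limma called 495 of 11716 genes in cerebellar vessels, 124 higher and 371 lower, and 167 changed more than 2-fold. The groups did not overlap for 22.1% of genes, against 10% by chance. The count was 327 without control cerebellar replicate 2 and 302 without knockout cerebellar replicate 3, and 794 with every probe set on its own.

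The mean of both regions per mouse asked which changes held at the level of the animal. Smooth muscle genes were lower here as well (30 of 40 markers; adjusted p = 0.199 with an estimated correlation). Myh11 fell by 1.74 log2 (SE 0.12, n = 3 mice per group) and Casq2 by 2.88 (SE 0.16). Synpo2l fell by 3.68 (SE 0.06), at least 6.74-fold, and Cacna1h, a neighbour of Notch3, by 4.22 (SE 0.12), at least 12.5-fold. Ang rose by 8.71 (SE 0.10), at least 287-fold, Rpgrip1 by 4.78 and Eme2 by 3.58, with 0.09 and no call on its second probe set. Ccr6 was at -6.91, at least 65.3-fold lower, and Adamdec1 at -6.11, at least 24.1-fold lower. Other higher genes were Lrmda (2.50, at least 4.43-fold), Ap1s3 (2.33, at least 3.79-fold), Fez1 (2.25), Pam (2.22), H2-DMa (2.18), Hddc3 (2.16), Zfp994 (2.09) and Glrp1 (1.95). Other lower genes were Ephx3 (-4.40), C1s1 (-3.36), Cyp2e1 (-3.34), Susd5 (-3.33), Gpr20 (-2.79) and Slc22a2 (-2.74, at least 5.01-fold lower). Pam was not called in the runs without any control mouse or without knockout 2 or 3, with no filter, with the replicate block or with Xist as a covariate, and Hddc3 was not called without control 1 or 2 or with no filter.

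On mouse means 30 of 40 smooth muscle markers fell and 10 were not called (36 lower adjusted over the list alone), with a median of -1.09 (camera adjusted p = 2.22e-34; adjusted p = 0.199 with an estimated correlation). Members that were not called included desmin (Des, -0.39), Smtn (-0.22), Cald1 (-0.21) and Tinagl1 (0.14). Without the 5 genes that are no independent evidence 25 of 35 fell, with a median of -0.94. Of 27 pericyte markers 13 fell (20 adjusted over the list alone; median -0.55, camera adjusted p = 1.98e-15; adjusted p = 0.199 with an estimated correlation), and 8 did without control 1, 8 without knockout 3 and 20 with 12 arrays as independent. Rgs5 (-0.06), Kcnj8 (-0.07) and Abcc9 (-0.04) were not called. Of 20 ion channels 7 fell (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.28e-08; adjusted p = 0.199 with an estimated correlation), and 3 did with the filter at the 75th percentile; without Cacna1h 6 of 19 fell (camera adjusted p = 3.63e-07). Of 18 Notch targets 6 fell (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00781; adjusted p = 0.199 with an estimated correlation), and 3 did without knockout 3 or with no filter. Without Grip2 and Nrip2, no independent evidence as above, 4 of 16 fell and the list was not called (camera adjusted p = 0.252). Limma called 0 of 25 microglia markers here, with 13 at an unadjusted p under 0.05 and 9 adjusted over the list alone, at a median of 0.46 (camera adjusted p = 6.45e-09; adjusted p = 0.626 with an estimated correlation), and 2 were called without control 3 or without knockout 2. The microglia count was 1 with the 75th percentile filter, 4 with array weights or the replicate block, 6 with the mouse as random replicate block and 10 with 12 arrays as independent. Camera also called immediate early genes downward (2 of 26 fell, Fosl2 at -0.99 and Atf3 at -0.95, and 8 lower and 1 higher adjusted over the list alone; adjusted p = 6.25e-05; adjusted p = 0.199 with an estimated correlation), with 0 called without control 1 or knockout 3 and 1 without knockout 1 or 2. Their count was 0 with the Xist covariate, 1 with no filter, 4 with the 75th percentile filter or the mean of probe sets, 6 with array weights, 7 with the mouse as random replicate block and 9 with 12 arrays as independent. Endothelial (1 higher and 1 lower of 33, 2 and 1 adjusted over the list alone) and astrocyte markers (1 higher and 1 lower of 21, 3 and 1 adjusted over the list alone) were called upward at medians of 0.08 and 0.23, and interferon genes, with 0 of 27 called by limma (8 at an unadjusted p under 0.05), downward at -0.16, each at an adjusted p of 0.00599. With an estimated correlation the adjusted p was 0.504 for endothelial, 0.823 for astrocyte and 0.823 for interferon genes. The endothelial count was 0 without control 1 or 2 and 1 without any other mouse, and the astrocyte count 1 without control 1 or knockout 2 or with no filter. The endothelial count was 1 with no filter, centred or quantile-normalised arrays, the replicate block or the Xist covariate. With 12 arrays as independent 5 endothelial, 5 astrocyte and 2 interferon genes were called, and with the mouse as random replicate block 1 interferon gene.

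Of the lists that camera did not call on mouse means, fibroblast genes had 4 higher and 3 lower of 36 (4 and 4 adjusted over the list alone). Col6a1 (1.55), Col6a2 (1.18), Col3a1 (0.77) and Ogn rose and Tagln (-0.94) fell; the 7 calls became 3 without control 2 or knockout 3 and 4 with no filter. Among 23 PDGF and VEGF genes 5 fell, led by Pgf (-1.34) and S1pr3 (-1.10), with 6 lower and 1 higher adjusted over the list alone. Notch3 and Dtx3 fell among 23 Notch receptors and ligands (2 lower and 1 higher adjusted over the list alone), and Tgfb3 (-1.07) among 24 TGF-beta genes (4 lower and 3 higher adjusted over the list alone). Col4a5 (-0.39) fell among 27 basement membrane genes (3 lower and 1 higher adjusted over the list alone), but not without control 3 or any one knockout mouse, and 2 were called without control 1. Basement membrane calls were 0 with the mean of probe sets or the replicate block, 2 with the 75th percentile filter or array weights, 3 with the Xist covariate, 4 with the mouse as random replicate block and 6 with 12 arrays as independent. Map2 (-0.70) fell among 20 neuron markers (1 lower and 1 higher adjusted over the list alone), and Rarres2 (-1.01) among 19 choroid plexus markers (1 adjusted over the list alone). Gabra6 (0.73) rose among 14 cerebellar neuron markers (2 higher and 2 lower adjusted over the list alone), with 2 called without knockout 2, with centred arrays, trend and robust eBayes or the replicate block, 3 with array weights, 12 arrays as independent or the mouse as random replicate block and 0 with the 75th percentile filter. Limma called 0 of 34 blood-brain barrier, 16 Wnt, 19 endothelial leak, 22 arterial, 16 venous, 22 hypoxia, 8 cell cycle, 9 forebrain neuron, 11 oligodendrocyte, 16 leukocyte and 6 red blood cell and platelet genes. Unadjusted p under 0.05 held for 3, 6, 3, 6, 2, 5, 0, 2, 2, 1 and 0 of them. Within lists adjusted alone, 1 Wnt gene was higher, and 3 Wnt, 1 venous and 2 forebrain genes were lower; 1 blood-brain barrier gene was called without control 1 or knockout 2, with the 75th percentile filter or either replicate block, and 2 were with 12 arrays as independent. Median and mean differed in sign for the Wnt (0.05 and -0.01), arterial (0.08 and -0.01), TGF-beta (0.05 and -0.04), PDGF and VEGF (0.03 and -0.17) and neuron lists (0.04 and -0.01). For endothelial leak (-0.03) and red blood cell genes (-0.01) the test pointed upward against a negative median.

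Limma called 472 of 11716 genes on mouse means, 120 higher and 352 lower, 162 of them by more than 2-fold. The groups did not overlap for 26.3% of genes, against 10% by chance. The count was 289 without control 1, 274 without control 2, 278 without knockout 1 and 237 without knockout 3; it was 312 with no filter, 765 with every probe set on its own, 1549 with all 12 arrays as independent and 906 with the mouse as random replicate block.

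The regions were then set side by side. Genes such as Ang, Rpgrip1, Ccr6, Adamdec1 and Ephx3 were called in both, and 344 genes were shared, 344 of them in the same direction. The overlap held 70 higher genes, where 3.04 would be shared if calls were independent, and 274 lower genes against 14.6. Of 899 genes called in either region 862 (95.9%) had the same sign in both. Across all 11716 genes the log2 fold changes correlated with r = 0.794 (SD over mice left out 0.0308). Genes are not independent replicates, and arrays of one mouse share its chance values, so calls in the 2 regions are not independent and the 3.04 and 14.6 are too low. Other splits gave r up to 0.723. A test added after this result was seen took the group means off each array and regrouped the mice in 9 other ways. Shared mice alone gave r from 0.396 to 0.639, and 62.3% of genes (median) with the same sign against 71.3%. The covariance was at most 0.0296 against 0.110, so the agreement exceeded what shared mice gave, though much of r can come from them.

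**Figure D3:**
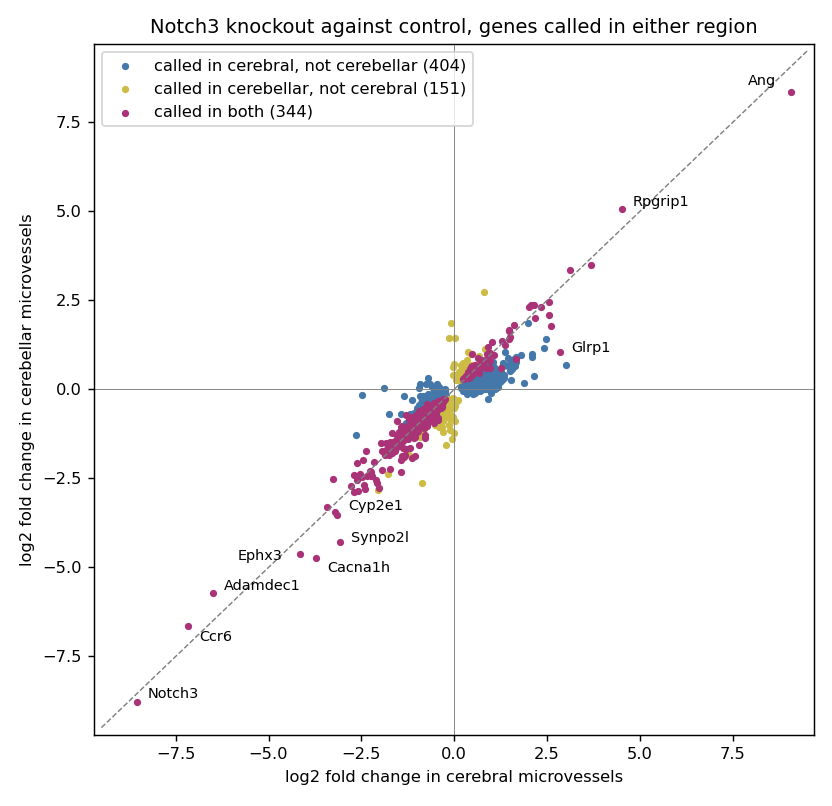
Log2 fold change, knockout against control, in cerebral (horizontal) and cerebellar (vertical) vessels for the 899 genes called in either region, with a dashed line of equal change.

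The difference of the knockout effect between regions asked for which genes that effect differed. Dmp1, an acidic protein of mineralised matrix, differed by 2.33 log2 (SE 0.27, n = 3 arrays per group, adjusted p = 0.0172), with means of 7.78 and 5.30 in control and knockout cerebral vessels and of 8.13 and 7.99 in cerebellar vessels. Gabra6 differed by 1.40 (SE 0.16, adjusted p = 0.0172), reading 5.06 in control and 6.50 in knockout cerebellar vessels and 3.81 and 3.84 in cerebral vessels. Ebf2 (-1.32), Dpt, the matrix protein dermatopontin (-1.23, adjusted p = 1.68e-05), and Zfpm2 (-0.74) differed the other way. Control cerebellar vessels read 3.71, 3.65 and 3.59 for these 3 genes and the other groups at most 2.82, close to the overall median of 3.27. Among the smallest p that were not called were Ppp1r26 (-0.71, adjusted p = 0.0888), Glrp1 (-1.81, 0.0993), Pvalb (1.94, 0.325) and Lmntd2 (0.43, 0.405). The regions share mice, and with the mouse as replicate block 4 genes were called, without Dmp1, Gabra6 and Zfpm2. Limma called 5 of 11716 genes, 2 higher and 3 lower, with 546 at an unadjusted p under 0.05.

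Lists differed between regions only by camera at its preset correlation. Microglia markers had a median difference of -0.64 (adjusted p = 2.79e-17; adjusted p = 0.512 with an estimated correlation), astrocyte markers one of 0.33 (adjusted p = 0.00195; adjusted p = 0.664 with an estimated correlation) and cerebellar neuron markers one of 0.25 (adjusted p = 4.61e-04; adjusted p = 0.179 with an estimated correlation). Pericyte markers, at 0.12, were not called (camera adjusted p = 0.0541), nor were smooth muscle markers, at -0.03. Limma called 0 members of each list but that of cerebellar neurons, where Gabra6 was called, with at most 10 members of a list, the microglia markers, at an unadjusted p under 0.05. Within single lists 3 cerebellar neuron and 2 neuron markers were higher and 1 ion channel was lower. Median and mean differed in sign for immediate early genes (-0.01 and 0.03), and arterial markers tested downward at a median of 0.02. With an estimated correlation camera called 0 lists (2 at an unadjusted p under 0.05), and fry called 0 (2 unadjusted). With the mouse as replicate block 7 lists were called; with no filter 2 genes and 5 lists were called and with the filter at the 75th percentile 0 genes. The count of 5 became 1 without control cerebral replicate 3, without knockout cerebral replicate 1 and without each knockout cerebellar replicate, 2 without control cerebellar replicate 2 or knockout cerebral replicate 3, and 20 without knockout cerebral replicate 2.

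Some of the most changed genes are neighbours of Notch3 on chromosome 17. Within 20 Mb lie Eme2, H2-DMa and Zfp994, which were higher, and Ephx3, Cacna1h and Slc22a2, which were lower; Ccr6 and Tmem242 lie on chromosome 17 outside this window. Ang, Rpgrip1, Lrmda, Adamdec1 and Synpo2l share chromosome 14, and Hebp1 and C1s1 share chromosome 6. Of 380 tested genes in the window 47 (12.4%) were called in any of the 3 knockout comparisons, against 876 of 11300 others (7.75%), an odds ratio of 1.68 (95% interval 1.20 to 2.30, two-sided Fisher's exact p = 0.00189). Of these 47 genes 26 were higher and 21 lower on mouse means, and 0 were in the smooth muscle or pericyte marker lists, but 1, Cacna1h, leads the smooth muscle ion channels. The arrays read transcripts through fixed probes, so a sequence difference under a probe changes a value as well; among the called neighbours, probe sets of Zfp945 gave -2.10, -0.79 and 5.76 on mouse means and those of Tbc1d24 -0.99, 0.09 and 0.97.

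The regions were also compared within the control mice, to describe what sets cerebellar vessels apart. Of 26 immediate early genes 12 were higher in cerebellar vessels, and the list was called with an estimated correlation (adjusted p = 0.00395). Of 27 pericyte markers 12 were, in a list not called with it (adjusted p = 0.0577). Fosb, a transcription factor of the immediate early class, was higher by 3.59 log2 (SE 0.33, n = 3 arrays per group), at least 9.34-fold, and the chemokine Cxcl2 by 3.91 (SE 0.36), with 1 of 3 cerebral arrays at or under 3.27. Dendrin (Ddn), a neuronal protein of the forebrain, was at -4.19 (SE 0.61), at least 10.3-fold lower. Also higher were Dlk1 (3.09, at least 8.38-fold with 2 of 3 cerebral arrays so low), the melanocortin receptor partner Mrap2 (2.98), the fatty acid carrier Fabp3 (2.97), Sema3b (2.75), the glutamate receptor subunit Gria4 (2.55), the nuclear receptor Esrrg (2.52), Slc6a15 (2.30), Ccl3 (2.27), Lgi1 (2.20) and A2m (2.17). Also lower were Chst2, Hpcal4 (-2.23, at least 3.01-fold), Alx1 (-2.14, at least 2.97-fold), Upk1b (-1.81), neuritin (Nrn1, -1.79), neurocan (Ncan, -1.46), the microglia gene Siglech (-1.34), Chrdl1 (-1.27), Gnao1 (-1.22, at least 1.88-fold), Ism1 (-1.07) and Ranbp3l (-1.04). Among the runs that tested the gene, at least 1 ended the call of 15 of these 24 genes. Of 7 named genes with several probe sets 0 had opposite signs, but 6 had a probe set that was not called when all were tested: Chrdl1 (-0.38, and also its -1.27), Chst2 (-0.50), Ism1 (-0.68), Ncan (-2.88), Ranbp3l (-0.19) and Upk1b (-0.85).

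Of 26 immediate early and stress genes 12 were higher and 14 not called (14 higher adjusted over the list alone), led by Fosb, Socs3 (1.98), Junb (1.76) and Egr1 (1.36), with a median of 0.58, and the list was called with the preset and with an estimated correlation (adjusted p = 2.59e-17 and 0.00395). Pericyte markers were higher in 12 of 27 cases (21 adjusted over the list alone; median 0.51, camera adjusted p = 1.75e-21; adjusted p = 0.0577 with an estimated correlation), led by Lamb1 (1.36), Abcc9 (1.02), Nodal (0.98) and Kcnj8 (0.84). The count was 3 without control cerebellar replicate 2 and 20 with array weights or the mouse as replicate block. Markers of other cells moved with region. Choroid plexus markers were higher in 5 of 19 cases (17 adjusted over the list alone; median 1.08, camera adjusted p = 1.43e-15; adjusted p = 0.147 with an estimated correlation), with Slc4a5 at 2.05 and Kcne2 at 1.61. Fibroblast genes were higher in 6 of 36 (15 adjusted over the list alone; median 0.26, camera adjusted p = 5.25e-09; adjusted p = 0.117 with an estimated correlation), with Lum at 1.71 and Dcn at 1.16, and astrocyte markers in 4 of 21 (9 higher and 2 lower adjusted over the list alone; median 0.36, camera adjusted p = 4.62e-04; adjusted p = 0.403 with an estimated correlation), with Aldh1l1 at 1.69 and Aqp4 at 1.59. Microglia markers were lower, with 1 of 25 called, Siglech (11 lower adjusted over the list alone; median -0.59, camera adjusted p = 1.57e-10; adjusted p = 0.325 with an estimated correlation). Without single arrays the choroid plexus count was 2, 3 and 1 for control cerebral replicates 1, 2 and 3 and 3, 0 and 0 for control cerebellar replicates 1, 2 and 3. The fibroblast count was 2 without control cerebral replicate 1, 3 without cerebral replicate 3 or cerebellar replicate 1 and 0 without cerebellar replicate 2. The astrocyte count was 1 without cerebellar replicate 2 and 2 without any other array but cerebral replicate 3. Siglech was not called without cerebral replicate 1 or 3 or cerebellar replicate 2 or 3, and without cerebral replicate 2 the microglia count was 2. With the mouse as replicate block 12 microglia, 16 choroid plexus, 14 fibroblast and 7 astrocyte markers were called, and with array weights 14, 14, 14 and 7. With no filter 2 choroid plexus, 2 fibroblast and 2 astrocyte markers were called, and 2 microglia markers were with the 75th percentile filter, centred or quantile-normalised arrays or trend and robust eBayes.

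Camera called 8 further lists between regions in controls. Ion channels were higher (4 of 20, 8 higher and 1 lower adjusted over the list alone, Cacna1h at 1.49; camera adjusted p = 6.66e-06; adjusted p = 0.0848 with an estimated correlation), as were basement membrane genes (3 of 27, 4 adjusted over the list alone, Lama2 at 1.03; camera adjusted p = 2.28e-05; adjusted p = 0.231 with an estimated correlation), Notch targets (2 of 18, Bcl2 at 0.52 and Pdgfrb at 0.44, 6 adjusted over the list alone; camera adjusted p = 0.00637; adjusted p = 0.0848 with an estimated correlation) and cerebellar neuron markers (2 of 14, Neurod1 at 1.28 and Gabra6 at 1.26, 5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0167; adjusted p = 0.166 with an estimated correlation). Smooth muscle markers were higher on balance with 0 of 40 called by limma (17 at an unadjusted p under 0.05, 6 adjusted over the list alone; camera adjusted p = 1.65e-06; adjusted p = 0.387 with an estimated correlation). Wnt (0 of 16), endothelial (0 of 33) and blood-brain barrier genes (0 of 34), with 7 each at an unadjusted p under 0.05 by limma, were lower on balance, at camera adjusted p of 4.62e-04, 0.00500 and 0.0167, with adjusted p = 0.166, 0.377 and 0.409 with an estimated correlation. The Notch target count was 1 without control cerebral replicate 1, 5 without cerebral replicate 2 and 0 without cerebellar replicate 2, the smooth muscle count 6 without cerebral replicate 2 and 1 without cerebellar replicate 1 or 3, and the cerebellar neuron count 1 without cerebral replicate 1 or 3 or cerebellar replicate 1 or 3. Without cerebellar replicate 3 the endothelial count was 1. With the mouse as replicate block 8 smooth muscle, 8 ion channel, 4 cerebellar neuron, 1 endothelial and 3 blood-brain barrier genes were called, and with array weights 12, 9, 4, 2 and 2, with 6 Notch targets and 5 basement membrane genes. The smooth muscle count was 1 with quantile normalization and 2 with the 75th percentile filter or trend and robust eBayes, and the cerebellar neuron count 1 with no filter and 0 with the 75th percentile filter.

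Among the lists that camera did not call in controls, Dlk1 was higher of 23 Notch receptors and ligands (1 higher and 1 lower adjusted over the list alone), Cxcl1 (1.57) of 19 endothelial leak genes and Pgk1 (0.42) of 22 hypoxia genes (1 each adjusted over the list alone). Pgf (0.97), Pdgfrb and S1pr3 were higher of 23 PDGF and VEGF genes (6 higher and 2 lower adjusted over the list alone). Limma called 0 of 22 arterial, 16 venous, 24 TGF-beta, 27 interferon, 8 cell cycle, 20 neuron, 9 forebrain neuron, 11 oligodendrocyte, 16 leukocyte and 6 red blood cell and platelet genes. Unadjusted p under 0.05 held for 2, 3, 7, 0, 1, 5, 2, 1, 0 and 0 of them, and adjusted over the list alone 3 TGF-beta genes and 1 forebrain gene were higher. Median and mean differed in sign for the PDGF and VEGF (-0.03 and 0.13) and hypoxia lists (-0.02 and 0.02), and endothelial leak genes tested upward at a median of -0.03.

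Limma called 268 of 11716 genes, 229 higher and 39 lower, 104 of them by more than 2-fold, with 21.0% of genes without overlap against 10% by chance. With the mouse as replicate block 915 genes were called; 160 were with no filter and 1078 with array weights. The count was 129 and 131 without control cerebral replicates 1 and 3 and 79 and 143 without control cerebellar replicates 2 and 3.

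Knockout mice were compared in the same way, and 23 of 25 microglia markers were lower in their cerebellar vessels. The count was 13 or 14 without any one of 4 of the 6 arrays and 17 or 23 without the other 2, and the list was not called with an estimated correlation (adjusted p = 0.154). P2ry12, the purine receptor of resting microglia, was at -1.74 (SE 0.23, n = 3 arrays per group) and Siglech at -1.97, while Dlk1 was higher by 4.80 (SE 0.55), at least 25.7-fold, and Cxcl2 by 4.25 (SE 0.36), at least 13.8-fold with 2 of 3 cerebral arrays at or under 3.27. Gabra6 (2.66, SE 0.12) and Pvalb (2.70, at least 3.19-fold) were higher as well. The other higher genes were Dpep1 (3.52), Nfkbid (3.32), Frrs1l, a protein of glutamate receptor complexes (3.23, with 1.92 and no call on a second probe set), Fabp3 (3.04), Mrap2 (3.04), the glucocorticoid enzyme Hsd11b1 (2.81), Gria4 (2.79) and Dmp1 (2.69). Lower were Ddn (-4.79, at least 16.3-fold), Upk1b (-3.07), Liph (-2.97), Hpcal4 (-2.56, at least 5.13-fold with 2 of 3 cerebellar arrays so low), Glrp1 (-2.38), the prostaglandin receptor Ptger3, Bank1 (-2.24), Cd300a (-2.23), Abcc3 (-2.19), Kif5a (-2.11), Ccdc88b (-2.08, at least 2.51-fold) and the fructose transporter Slc2a5 (-2.05). Hsd11b1, Liph, Hpcal4, Abcc3 and Kif5a lost their call in at least 1 of the alternatives and left-out arrays that tested them.

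Microglia markers were lower in 23 of 25 cases in knockout mice (25 adjusted over the list alone; median -1.19, camera adjusted p = 1.10e-24; adjusted p = 0.154 with an estimated correlation), and in 13 without knockout cerebral replicate 1 and 14 each without cerebral replicate 3, cerebellar replicate 2 or cerebellar replicate 3. Immediate early genes were higher in 15 of 26 (17 adjusted over the list alone), Fosb at 2.23 (at least 3.15-fold) and Socs3 at 1.66, and called with the preset and with an estimated correlation (adjusted p = 1.72e-14 and 0.00771). Pericyte markers were higher in 19 of 27 (20 adjusted over the list alone; median 0.73, camera adjusted p = 7.82e-19; adjusted p = 0.0642 with an estimated correlation), Lamb1 at 1.47 and Ndufa4l2 at 1.07. Higher too were fibroblast genes (13 of 36, 15 adjusted over the list alone, Lum at 2.11; camera adjusted p = 1.93e-09; adjusted p = 0.131 with an estimated correlation), choroid plexus markers (7 of 19, 14 adjusted over the list alone, Slc4a5 at 1.90; camera adjusted p = 8.90e-11; adjusted p = 0.229 with an estimated correlation), astrocyte markers (10 of 21, 11 higher and 1 lower adjusted over the list alone, Gdf10 at 2.43 and Aqp4 at 2.24; camera adjusted p = 7.36e-07; adjusted p = 0.279 with an estimated correlation) and cerebellar neuron markers (6 of 14, 7 higher and 1 lower adjusted over the list alone, Calb1 at 2.02 (at least 3.46-fold) and Neurod1 at 1.79; camera adjusted p = 1.49e-04; adjusted p = 0.0642 with an estimated correlation). Basement membrane genes (6 of 27, 8 adjusted over the list alone, Lama2 at 1.41; camera adjusted p = 1.54e-06; adjusted p = 0.229 with an estimated correlation), smooth muscle markers (4 of 40, 5 adjusted over the list alone, Casq2 at 1.55; camera adjusted p = 4.48e-04; adjusted p = 0.609 with an estimated correlation) and ion channels (5 higher and 1 lower of 20, 6 and 2 adjusted over the list alone, Kcnma1 at -1.05; camera adjusted p = 0.00515; adjusted p = 0.229 with an estimated correlation) were higher on balance. Wnt genes were lower (2 of 16, 3 adjusted over the list alone, Fgfbp1 at -0.99, its cerebellar arrays under 3.27; camera adjusted p = 0.0172; adjusted p = 0.333 with an estimated correlation). Without single arrays the choroid plexus count was 2 (knockout cerebral replicate 1, cerebral replicate 3 or cerebellar replicate 2), 15 (cerebral replicate 2) or 4 (cerebellar replicate 3), the astrocyte count 6 (cerebral replicate 1 or cerebellar replicate 3) and the smooth muscle count 1 or 2 (any array but cerebral replicate 2). The choroid plexus count was 15 with the mouse as replicate block and 4 with no filter, and with the 75th percentile filter 3 ion channels and 1 cerebellar neuron marker were called.

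Among the lists that camera did not call in knockout mice, Dlk1 was higher of 23 Notch receptors and ligands and Cxcl1 (2.07) of 19 endothelial leak genes (1 each adjusted over the list alone). Bcl2 (0.65) and Pdgfrb (0.66) were higher and Hes5 (-0.66) lower of 18 Notch targets (4 and 2 adjusted over the list alone). Pdgfra (1.21), Pgf (1.03), Pdgfrb and S1pr3 were higher of 23 PDGF and VEGF genes (4 higher and 1 lower adjusted over the list alone). Ccn1 (1.11) and Tgfbi were higher and Tgfbr1 (-0.77) lower of 24 TGF-beta genes (3 and 1 adjusted over the list alone). Pvalb was higher and Camk2a (-1.46, at least 2.35-fold) lower of 20 neuron markers, and Camk2a was also called of 9 forebrain neuron markers, as they were adjusted over the list alone. Slco2b1 (-0.32) was lower of 34 blood-brain barrier genes (1 adjusted over the list alone), but not without knockout cerebral replicate 1 or 3 or cerebellar replicate 2 or 3. Limma called 0 of 33 endothelial, 22 arterial, 16 venous, 22 hypoxia, 27 interferon, 8 cell cycle, 11 oligodendrocyte, 16 leukocyte and 6 red blood cell and platelet genes. Unadjusted p under 0.05 held for 2, 1, 2, 5, 2, 1, 4, 6 and 0 of them. In its list alone 1 cell cycle gene was lower, and without knockout cerebral replicate 2 the endothelial count was 1. With the mouse as replicate block 6 Notch targets, 3 blood-brain barrier and 2 interferon genes were called. The endothelial count was 1 with no filter, array weights or the Xist covariate and 2 with the mean of probe sets, and the interferon count 1 with the Xist covariate. Median and mean differed in sign for Notch receptors (-0.02 and 0.26) and hypoxia genes (0.01 and -0.02).

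Limma called 797 of 11716 genes between regions in knockout mice, 450 higher and 347 lower, 292 of them by more than 2-fold, with 25.4% of genes without overlap against 10% by chance. Of the genes called in controls 186 higher and 16 lower ones were called here in the same direction, where 8.80 and 1.16 would be shared if calls were independent. With the mouse as replicate block 1723 genes were called, and with no filter 508. The count was 366 and 416 without knockout cerebral replicates 1 and 3 and 397 and 464 without knockout cerebellar replicates 2 and 3.

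**Figure D4:**
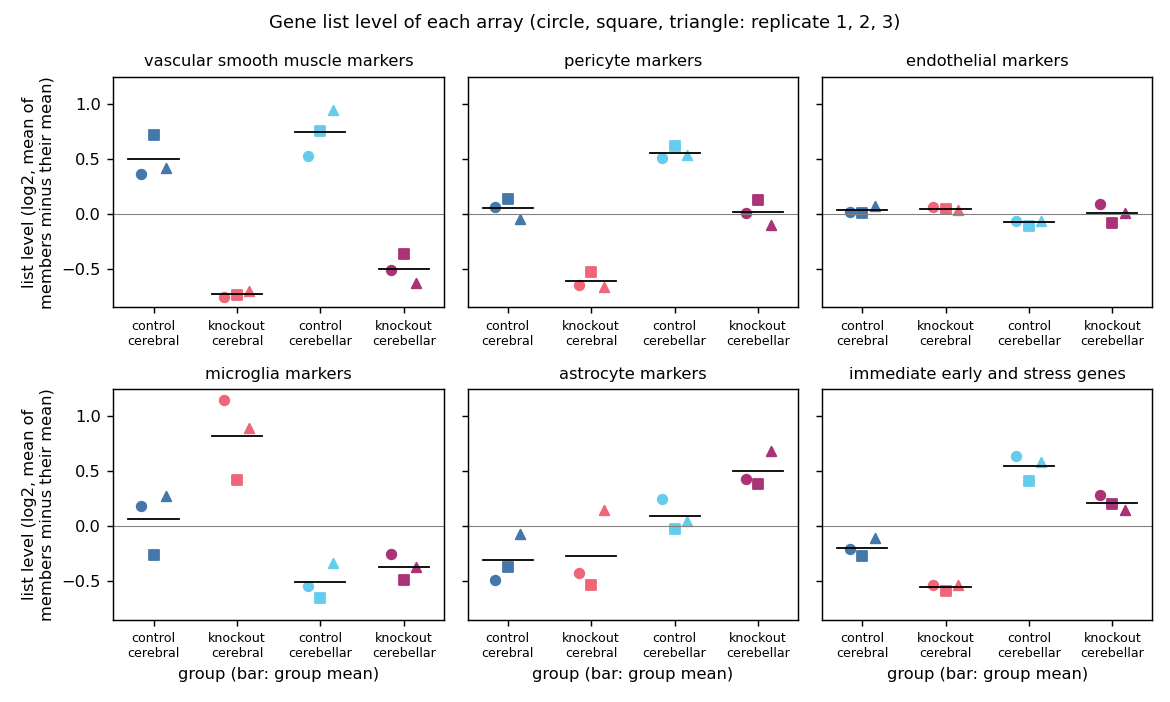
Level of 6 gene lists on each array, as the mean over members of their log2 value minus its mean over the 12 arrays, with a symbol for each replicate and bars for group means.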

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

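The points below are differences of the knockout effect between regions; the tests on microglia were chosen after their result was seen. Dmp1 differed by 2.33 log2, since it was lower in knockout than in control cerebral vessels and close to the control level in cerebellar vessels. Gabra6 differed by 1.40, with its highest level in knockout cerebellar vessels. Ebf2 (-1.32), Dpt (-1.23) and Zfpm2 (-0.74) read slightly above the overall median in control cerebellar vessels and under it in the other groups, so each difference rests on 1 group near background. The regions share mice, and with the mouse as replicate block 4 genes were called, without Dmp1, Gabra6 and Zfpm2. The calls of Dmp1, Gabra6, Ebf2 and Zfpm2 were each lost in at least 1 alternative or left-out array. That of Dpt was lost in none of those that tested it, but the filter at the 75th percentile left Dpt out and called 0 genes. As lists, cerebellar neuron markers (0.25) and astrocyte markers (0.33) were shifted toward a higher effect in cerebellar vessels and microglia markers (-0.64) toward a lower one. None of the 3 lists passed fry or camera with an estimated correlation.

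Microglia markers were higher in knockout cerebral arrays, and 3 explanations were tested. A lower share of vessel cells would raise markers of other cell types too, but the upper quartile of their 68 members was 0.249, under the microglia lower quartile of 0.55. Microglia carried over to differing extents between preparations may explain the shift. Members moved together within groups as this needs, with a mean correlation of 0.761, but microglia that vary between animals would give that too. It was the highest of 28 lists, before choroid plexus (0.608) and interferon genes (0.511), against at most 0.112 in 100 random sets. A knockout effect on microglia that differs between regions may explain it as well: the cerebral minus cerebellar level was higher in knockout mice by 0.61 (SE 0.17, 95% interval 0.129 to 1.10, 3 mice per group, 4 degrees of freedom), and by 0.67, 0.52 and 0.65 within the same numbers. This interval was added after a two-sided exact permutation test had given p = 0.1, the smallest it can give with 3 mice against 3. Since more carry-over into knockout cerebral preparations would give the same values, that source and a knockout effect both stay open.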

How the results depend on the processing

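Of the counts, gene list counts and correlations compared across settings, 53 values moved by more than the set margin and 91 did not. Camera with an estimated inter-gene correlation called 0 lists in cerebral vessels, 3 in cerebellar vessels, 0 on mouse means, 0 for the difference between regions, 1 between regions in controls and 1 in knockouts, against 8, 8, 9, 3, 14 and 11 with the preset; fry called 0 for the difference and 9 in controls. With every probe set on its own 1164 genes were called in cerebral vessels, 794 in cerebellar vessels and 765 on mouse means. Without the filter the counts were 312 on mouse means, 2 for the difference (with 5 lists), 160 between regions in controls and 508 in knockouts; the filter at the 75th percentile left 0 for the difference and raised the agreement between regions to r = 0.858. Array weights gave 1415 in cerebral vessels and 1078 between regions in controls, and the 6 cerebral arrays alone gave 310. With the number as replicate block the counts were 1127 in cerebral vessels, 719 in cerebellar vessels and 407 on mouse means. That block assumes a pairing across genotypes that the labels do not give. The mouse as fixed replicate block gave 915 between regions in controls, 1723 in knockouts and 7 lists for the difference. On mouse means, 12 arrays as independent gave 1549 and the mouse as random replicate block 906; the first counts each mouse more than once by construction. The Xist covariate, chosen after the data had been seen, gave 832, 563, 408, 6, 311 and 937. The causes of the other shifts were not tested.

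With each array or mouse left out, counts ranged from 439 to 870 in cerebral and 302 to 397 in cerebellar vessels. On mouse means the range was 237 to 473. Each was lowest without knockout 3 and highest without knockout 2, the only knockout without Xist. Leaving it out also changed the mix of sexes. The difference between regions ranged from 1 to 20 (without knockout cerebral replicate 2). Between regions the range was 79 (without control cerebellar replicate 2) to 239 in controls and 366 (without knockout cerebral replicate 1) to 1099 (without knockout cerebral replicate 2) in knockouts. The agreement ranged from r = 0.737 (without control 1) to 0.817 (without control 3), and the odds ratio near Notch3 from 1.64 to 1.72 over the other windows and probe set choices.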

Other observations

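The tests on mural markers and on probe sets near Notch3 were chosen after their results were seen, and the tests on the stretch around Notch3 and the splits before. Of the fibroblast list, 3 collagens picked after their values were seen rose in knockout vessels, Col6a1 by 1.46 log2 in cerebral and 1.64 in cerebellar vessels and Col6a2 by 1.02 and 1.34, and Col3a1 by 0.71 and 0.82. The fibroblast list had a median of -0.03 in cerebral and 0.03 in cerebellar vessels, and camera did not call it. Smooth muscle genes fell to different extents: on mouse means Kcnab1 fell by 2.56, Myh11 by 1.74 and Acta2 by 0.39, while the pericyte genes Rgs5, Kcnj8 and Abcc9 lay within 0.07 of 0.

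Mural cell markers were lower in knockout arrays. Other cells diluting the vessels would lower endothelial markers as well, but their median on mouse means was 0.0844. The scaling between arrays did not account for it, since the smooth muscle median nearest to 0 under the other scalings was -1.06 on mouse means (-0.996 in cerebral vessels). The spread was taken over members with control levels from 8.45 to 13. The interquartile range was 1.36 over 26 smooth muscle markers (median SE 0.118) and 0.485 over 21 pericyte markers (0.0998). Loss of cells need not lower markers alike, so this cannot decide. Fewer cells and a lower expression per cell, which was not tested, stay open.

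Called genes were more frequent near Notch3, with an odds ratio of 1.68. Genes of that stretch were not called more often between regions, with an odds ratio of 1.04 (29 of 380 against 832 of 11300). Sequence of another strain kept around Notch3 may be the source, as 4.27% of 11109 windows elsewhere had as high a share of called genes. Those windows overlap and lay on 10 of 20 chromosomes, with shares up to 19.1% on chromosome 15 and 18% on chromosome 6, so such stretches also occur far from Notch3. Probe sets that cover a strain variant are a candidate source too, since probe sets of a called gene differed by more than 1 log2 for 7 of 20 genes near Notch3 against 27 of 362 elsewhere (odds ratio 6.62, 95% interval 2.06 to 19.7, two-sided Fisher's exact p = 7.98e-04). Strain sequence itself was not analysed here, so each of these sources and an effect of Notch3 on its neighbours stay open.

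The 6 arrays of a comparison, or the 6 mice where both regions enter, can be split in 10 ways into 3 against 3, too few for a share under 0.05. In each case only the real split, 1 of the 10, gave a result as large. The real split called 748 genes in cerebral vessels against at most 2 in another split, 495 against 1 in cerebellar vessels, 472 against 0 on mouse means and 5 against 1 for the difference between regions. Between regions, where the 6 arrays came from 3 mice, it called 268 against 0 in controls and 797 against 0 in knockouts. The other splits that part all 3 pairs of same-numbered arrays called 0 genes in each comparison. The agreement between regions was r = 0.794 against at most 0.723.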
